A study of Homo sapiens with 6 samples.

How the data were processed

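The series holds RNA-seq of HT29, an established human colorectal adenocarcinoma cell line, carrying either a control short hairpin RNA (shCTRL, 3 libraries) or a hairpin against FITM2 (shFITM2, 3 libraries). Total RNA was extracted with Trizol and made into libraries with the NEBNext Ultra Directional kit, per the labels' protocols. The kit keeps the strand of each RNA, but the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Genes whose overlap holds the most reads relative to their own, and gene families with near-identical copies, are therefore named with that limit. Other named genes overlap genes with fewer reads, which are not given.

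The values are raw read counts per gene in a single table of all 6 libraries that the authors deposited. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1 without saying what each did, and name hg19 as the genome. The table's own gene positions are not those of hg19: of its 58978 genes, 58735 have an Ensembl identifier, and all 58735 have the GRCh38 position and strand that GENCODE release 29 gives for that identifier. The other 243 loci have no Ensembl identifier. Coordinates are given on GRCh38 as in the table. The values are whole numbers that sum to a different total in each library, from 16964075 to 18855731, and were treated as counts.

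Groups and replicate numbers came from the sample titles. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicates of a group were compared by a chi-square of their counts over 14671 genes. The chi-square per gene was 5.59, 20.2 and 28.5 for the pairs of shCTRL libraries and 2.35, 4.37 and 2.95 for the pairs of shFITM2 libraries. All lie above the value near 1 that sampling noise alone gives, so each library was counted as a separate sample.

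The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust fit, group as the sole term), with TMM normalization and Benjamini-Hochberg adjustment over all tested genes. Genes passed the edgeR expression filter with a minimum count of 10 and a minimum total of 15, which left 14809 genes. A gene was called at an adjusted p under 0.05, and a second count took those with an absolute log2 fold change of at least 1. Log2 fold changes are shFITM2 minus shCTRL and carry their standard error. CPM values are counts scaled to TMM library sizes, given as mean ± SD of the 3 libraries of a group. FITM2 also had an exact two-sided permutation test of log2 CPM (prior count 2), which with 20 arrangements of 3 against 3 libraries cannot fall below 0.1.

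Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. The 38 lists covered lipid droplets and lipid metabolism, the trans-Golgi network, interferon and antigen presentation, inflammation, stress, energy metabolism, cell cycle, ribosomes, intestinal differentiation, signalling, lysosomes, histones and markers of other cell types, and 34 had enough members. Counts of called members are given over all genes tested and adjusted over the list alone. The comparison, the tests, the lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. That rule named FITM2, a fixed set of 14 interferon-gamma, antigen presentation and lipid genes, the 10 protein-coding genes with the largest rise and the 10 with the largest fall, and up to 4 members with the smallest p of each reported list. The genes with the largest changes needed an adjusted p under 0.05, a mean of at least 5 CPM, and every shFITM2 library on the same side of every shCTRL library. Some genes that the rule names are not reported here.

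Fold changes followed the GC content of the transcripts, so a second fit was added after seeing the data. In it, a smoothing spline (6 degrees of freedom) of each library's log2 deviation on the GC content of 1 GENCODE transcript per gene (coding where there is one, then the longest) entered edgeR as a gene-by-library offset. This GC offset could be computed for 14635 genes, and 98.8% of tested genes had a GC value. A further fit took transcript length into the offset as well. The offset also removes any change of the cells that follows GC content.

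The alternatives chosen before the data were examined were DESeq2 size factors or library totals in place of TMM, no expression filter or a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a test against a 1.5-fold change, an adjusted p under 0.01, removal of mitochondrial genes, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Those added later are the fits with the GC offset and their own left-out libraries, block, estimated correlation and fry.

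The pipeline was tested on simulated counts drawn from the means and sizes of these libraries. With no GC trend, the group fit recovered 62.2% of 98 genes planted at 1.5-fold and 78.6% of 98 planted at 2-fold, and called 13 of 14337 unchanged genes. With the GC trend of the 6 libraries added, it called 5998 of 14335 unchanged genes (41.8%), against 16 of 14165 (0.113%) with the GC offset, which recovered 61.9% of the 1.5-fold and 79.6% of the 2-fold genes. All columns of the table that hold counts were used.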

Results

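HT29 colon cancer cells with a control hairpin (shCTRL) were compared with HT29 cells in which FITM2 was knocked down (shFITM2), by RNA-seq of 3 libraries per group. FITM2 is an endoplasmic reticulum membrane protein required for the budding of lipid droplets, and the series concerns lipid droplets, trafficking of the interferon-gamma receptor chain IFNGR1 and diacylglycerol of the trans-Golgi network. The shCTRL libraries held 18855731, 18342300 and 17176487 counts and the shFITM2 libraries 18263911, 17518562 and 16964075. No label names an interferon-gamma treatment of these cells.

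FITM2 mRNA was lower in every shFITM2 library, at 4.83, 5.98 and 4.95 CPM against 13.25, 10.55 and 10.44 CPM in shCTRL, which is 46% of control. Among mRNAs of metabolism, LDHA (a lactate dehydrogenase subunit), RRM2 (the regulatory subunit of ribonucleotide reductase) and SRM (spermidine synthase) fell, all called with and without the GC offset. Lists of DNA replication genes and of MYC targets and ribosome biogenesis genes were called lower in both fits at the preset correlation. Both calls were lost with an estimated correlation, in the group fit (adjusted p = 0.465 with an estimated correlation for both lists) and with the GC offset (adjusted p = 0.261 and 0.0807 with an estimated correlation). The lipid droplet, triacylglycerol synthesis, diacylglycerol and trans-Golgi lists held genes called in both directions and none of these lists was called by camera. IFNGR1 mRNA was lower in shFITM2, at 54.0 ± 1.51 CPM against 72.2 ± 5.18 (SD, n = 3 per group), but was not called when the GC trend of the libraries was removed.

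The FITM2 gene (ENSG00000197296, chromosome 20, 44302838 to 44311169, minus strand, GRCh38) had a log2 fold change of −1.12 ± 0.157 (SE; adjusted p = 0.000242, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its mean was 5.26 ± 0.631 CPM in shFITM2 and 11.4 ± 1.59 CPM in shCTRL (SD, n = 3), from 84 to 250 reads per library. It was −1.08 ± 0.15 with the GC offset (adjusted p = 7.65e-05). The exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

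**Figure D1:**
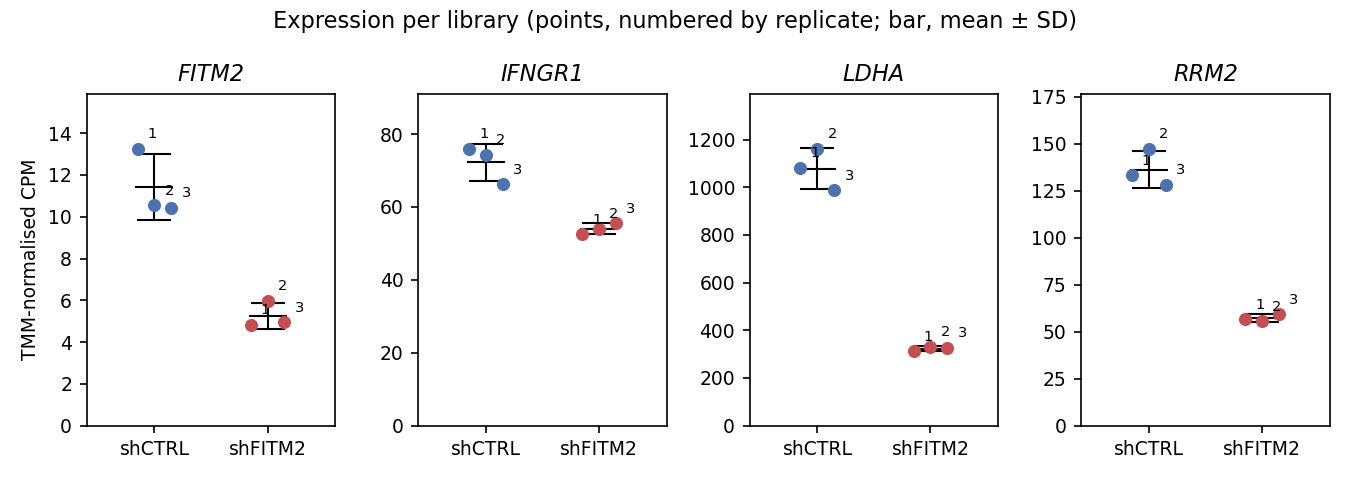
TMM-scaled CPM of FITM2, IFNGR1, LDHA and RRM2 in each of the 3 shCTRL and 3 shFITM2 libraries (points), with the mean and SD of each group. LDHA lies at 323 ± 9.41 CPM in shFITM2 against 1077 ± 86.4 in shCTRL, and FITM2 at 5.26 ± 0.631 against 11.4 ± 1.59.

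Of 14809 genes tested, 7205 were called (48.7%), 3583 higher and 3622 lower in shFITM2, and 780 of them by at least 2-fold, 639 higher and 141 lower. The fold changes followed transcript GC content. Across genes, which are not independent replicates, the Spearman correlation was 0.744. The median log2 fold change ran from −0.47 among the genes lowest in GC (27.9% to 38.7%) to 0.71 among those highest in GC (61.9% to 83.9%). The slope of log2 expression on GC, per 10 percentage points, was −0.27, −0.33 and −0.07 in the shCTRL libraries and 0.26, 0.23 and 0.18 in the shFITM2 libraries. The library of shCTRL replicate 3 lay between the others, at −9.7 on the first principal component (79.9% of variance) against −32.6 and −40.6 for the other shCTRL libraries and 23.7 to 31.1 for shFITM2.

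With the GC offset, 4227 of 14635 genes were called, 1837 higher and 2390 lower, and 258 by at least 2-fold. The same direction was called in both fits for 2595 genes, 1203 higher and 1392 lower, and the opposite direction for 305. A further 4260 genes were called in the group fit alone and 1327 with the GC offset alone. Without shCTRL replicate 3, the count of genes changed at least 2-fold was 1417 in the group fit. Without shFITM2 replicate 1, the count of genes changed in shFITM2 against shCTRL, GC-adjusted, was 2760.

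**Figure D2:**
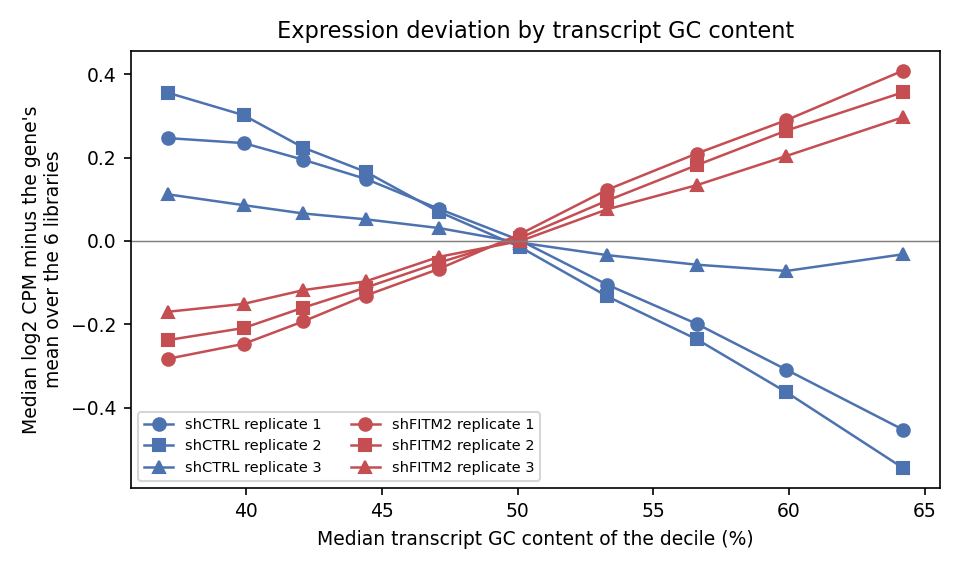
Median log2 deviation from the mean of the 6 libraries (vertical axis) for genes grouped into deciles of transcript GC content (horizontal axis, percent), with a line per library. The shFITM2 lines climb with GC content, at slopes of 0.18 to 0.26 per 10 points, the shCTRL replicate 1 and 2 lines descend, and shCTRL replicate 3 is the flattest at −0.07.

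Among the genes with the largest changes in the group fit, LDHA fell furthest there, by 1.74 on the log2 scale (SE 0.072; adjusted p = 4.01e-07, edgeR), and by 1.51 with the GC offset (SE 0.046; adjusted p = 1.07e-11). RRM2 had a log2 fold change of −1.25 ± 0.077 and −1.10 with the GC offset (adjusted p = 5.23e-06 and 5.38e-09). ATP5MD, a small membrane subunit of ATP synthase, had −1.30 and −1.22, and the metallothionein gene MT1E −1.37 and −1.59. SSR1, a subunit of the translocon-associated protein complex, had −1.33 and −0.97, the selenoprotein gene SELENOT −1.58 and −1.09, the small GTPase gene RAP1B −1.28 and −0.84, and TXNDC16 −1.29 and −0.85. All of these passed the test in both fits. GCSH, the H protein of the glycine cleavage system, had −1.44 (adjusted p = 0.0218) and −1.07 with the GC offset (adjusted p = 0.0896). Its call was also lost without shCTRL replicate 2, shFITM2 replicate 1 or shFITM2 replicate 2 (adjusted p = 0.0586, 0.0691 and 0.0642 for the GCSH log2 fold change).

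The largest rise was that of PSENEN, a subunit of gamma-secretase, at 2.85 ± 0.279 (adjusted p = 0.000157, edgeR) and 2.74 with the GC offset (adjusted p = 9.46e-05). FKBP2, a prolyl isomerase of the endoplasmic reticulum, had 2.67 ± 0.548 (adjusted p = 0.0142) and 2.03 (adjusted p = 0.0283), and the call was lost without shCTRL replicate 2 (adjusted p = 0.0599 for the FKBP2 log2 fold change). TPPP3 had 2.51 and 1.97, YPEL3 2.27 and 1.88, FAM207A 2.27 and 1.52, the TFIID subunit gene TAF10 2.22 and 1.55, C6orf48 2.16 and 2.10, EVA1B 2.07 and 1.32, the immunoproteasome subunit gene PSMB10 2.04 and 1.52, and CYP27A1, the mitochondrial sterol 27-hydroxylase, 2.01 and 1.48. These 8 genes were called in both fits. These 10 genes were low in control cells, from 2.05 CPM for EVA1B to 10.1 CPM for FKBP2. SELENOT, ATP5MD, EVA1B and PSENEN overlap SERP1, TAF5, SH3D21 and U2AF1L4 on the opposite strand, whose reads may be included.

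Most calls among genes of the interferon-gamma receptor and its signalling were lost with the GC offset. IFNGR1 had a log2 fold change of −0.42 ± 0.08 (adjusted p = 0.00133, edgeR) and −0.05 ± 0.058 with the GC offset (adjusted p = 0.582). IFNGR2, the second receptor chain, had 0.17 and −0.13 and was not called in either fit, nor were the receptor kinase genes JAK1 (−0.06 and 0.07) and JAK2 (−0.12 and 0.28). IRF1, an interferon-induced transcription factor gene, rose by 0.49 ± 0.104 and by 0.29 with the GC offset (adjusted p = 0.00255 and 0.0183). The phosphatase gene PTPN11 had −0.40 (adjusted p = 0.000869) and −0.10 (adjusted p = 0.0943). IFNGR2, JAK1, IRF1 and PTPN11 overlap TMEM50B, RAVER2, C5orf56 and RPL6 on the opposite strand. Of the 12 tested genes of this list, 2 were called higher and 5 lower, the same counts when adjusted over the list alone, with no call for the list (camera adjusted p = 0.547). When the offset was used, 1 was higher and 1 lower (adjusted over the list alone 1 and 0; adjusted p = 0.983, with a median and mean of −0.03 and a test direction upward).

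Several genes that respond to interferon-gamma rose. The interferon-gamma response list had 10 members higher and 3 lower of 27 tested, the same when adjusted over the list alone, and was not called (camera adjusted p = 0.273). With the GC offset 11 were higher and 2 lower (adjusted over the list alone 13 and 2), and the list was called (adjusted p = 0.0069; adjusted p = 0.265 with an estimated correlation). Its members called higher in both fits include PSMB10, the adhesion molecule gene ICAM1 at 1.47 and 1.10 with the GC offset, the guanylate-binding protein gene GBP2 at 0.80 and 0.90, and APOL2 at 0.78 and 0.59. CD274, which encodes PD-L1, had −0.30 (adjusted p = 0.369) and 0.05 (adjusted p = 0.902). The type I interferon-stimulated genes were called higher in 10 and lower in 6 of 34 members (camera adjusted p = 0.757), and in 5 and 3 with the GC offset (adjusted p = 0.734).

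In the MHC class I antigen presentation list, 10 of 22 members were higher and 3 lower (adjusted over the list alone 11 and 3), without a call for the list (camera adjusted p = 0.163). In the fit with the GC offset 6 were higher and 2 lower, in part other members, also when adjusted over the list alone (adjusted p = 0.125). HLA-E rose by 0.69 and by 0.41 with the GC offset (adjusted p = 7.99e-05 and 3.67e-05, edgeR). HLA-C had 0.54 (adjusted p = 0.000843) and −0.002 (adjusted p = 0.992), and HLA-B 0.87 ± 0.267 (adjusted p = 0.0183) and 0.41 (adjusted p = 0.204). The HLA-B call was lost without shCTRL replicate 1, shCTRL replicate 2, shFITM2 replicate 1 or shFITM2 replicate 3 (adjusted p = 0.078, 0.0537, 0.0609 and 0.0715 for the HLA-B log2 fold change). B2M, the shared light chain, had 0.08 (adjusted p = 0.307) and 0.46 (adjusted p = 0.000163). The chaperone gene CANX had −0.42 (adjusted p = 0.000503) and −0.09 (adjusted p = 0.106). HLA-B and HLA-C overlap on the same strand, and HLA genes share long stretches of sequence, so reads may be split among them.

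Lipid droplet genes went both ways. Of 19 tested members of the lipid droplet coat and biogenesis list, 6 were higher and 7 lower (adjusted over the list alone 6 and 8), and the list was not called (camera adjusted p = 0.771). Under the GC offset 2 were higher and 4 lower, in part other members (adjusted over the list alone 2 and 4; adjusted p = 0.983). Its median and mean were 0.21 and 0.05 while the test pointed down, and −0.03 and 0.01 with the GC offset. LDAH, a droplet-associated hydrolase, fell by 0.79 on the log2 scale and by 0.48 with the GC offset (adjusted p = 0.000117 and 0.000294, edgeR), and the acyl-CoA synthetase gene ACSL3 by 0.55 and 0.12 (adjusted p = 0.000243 and 0.0462). The ACSL3 call was lost when length was adjusted for as well (−0.10, adjusted p = 0.0741). RAB18 had −0.58 and −0.14, and the droplet coat gene PLIN3 0.63 and 0.18, neither called with the GC offset (adjusted p = 0.217 and 0.143). PLIN2, the main droplet coat protein outside adipocytes, had −0.32 ± 0.131 (adjusted p = 0.0664) and −0.31 (adjusted p = 0.064), and was called without shCTRL replicate 3, where the PLIN2 log2 fold change was −0.43 (adjusted p = 0.00116).

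Enzymes of triacylglycerol synthesis were called higher in 3 and lower in 4 of 17 members, the same when adjusted over the list alone (camera adjusted p = 0.913), and in 1 and 3 with the GC offset, again the same over the list alone (adjusted p = 0.734). DGAT1, which makes triacylglycerol from diacylglycerol, had 0.50 (adjusted p = 0.000419, edgeR) and −0.18 with the GC offset (adjusted p = 0.0648), so that its direction turned, and DGAT2 had 0.20 and −0.16, not called in either fit. GPAT3 had −0.73 and −0.51 and AGPAT5 −0.56 and −0.26, acyltransferases of the pathway called lower in both fits, while AGPAT1 had 0.47 and 0.21 and was called in the group fit alone. Diacylglycerol metabolism and signalling had 8 members higher and 7 lower of 30, also over the list alone (camera adjusted p = 0.783), and 3 and 4 with the GC offset (adjusted over the list alone 3 and 3; adjusted p = 0.877). Phospholipase gene PLD2 rose by 0.95 and by 0.50 with the GC offset and PLCG1 by 0.62 and 0.31, whereas PLCE1 had −0.71 and −0.44 and the diacylglycerol kinase gene DGKH −0.62 and −0.19. These 4 genes passed the test in both fits. DGAT1 overlaps HSF1, and PLCG1 overlaps ZHX3, on the opposite strand.

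Trans-Golgi network and secretory sorting genes were called higher in 12 and lower in 14 of 39 members (adjusted over the list alone 12 and 15, camera adjusted p = 0.869). With the GC offset the counts were 4 and 2, also over the list alone (camera adjusted p = 0.734). The alternative test fry did not call the list in the group fit (adjusted p = 0.277). It called the list higher with the GC offset (fry adjusted p = 0.0364) and with length as well (fry adjusted p = 0.0027). AP1S1, a subunit of the clathrin adaptor AP-1, rose by 0.77 and by 0.43 with the GC offset (adjusted p = 4.69e-05 and 1.91e-05, edgeR). ARFIP2 had 0.53 and 0.33 and the phosphoinositide phosphatase gene SACM1L −0.64 and −0.24, both called in both fits. The GTPase gene ARFRP1 had 0.86 (adjusted p = 4.61e-05) and 0.13 (adjusted p = 0.514). ARFIP2 and ARFRP1 overlap TIMM10B and ZGPAT on the opposite strand.

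In the MYC targets and ribosome biogenesis list, 13 of 27 members were lower and 1 higher, the same over the list alone (camera adjusted p = 0.0205; adjusted p = 0.465 with an estimated correlation). After GC adjustment 18 were lower and none higher (20 lower when adjusted over the list alone; adjusted p = 1.48e-13; adjusted p = 0.0807 with an estimated correlation). SRM had −1.16 ± 0.097 and −1.85 ± 0.077 with the GC offset (adjusted p = 2.46e-05 and 7.32e-10, edgeR), the ribosome processing gene UTP20 −0.84 and −0.55, the RNA polymerase I subunit gene POLR1B −0.66 and −0.47, and NOP58 −0.63 and −0.29. Of 32 DNA replication genes, 20 were lower and 3 higher (adjusted over the list alone 21 and 6), and the list was called lower (camera adjusted p = 0.00144; adjusted p = 0.465 with an estimated correlation). After GC adjustment 26 were lower and none higher, also over the list alone (adjusted p = 3.48e-13; adjusted p = 0.261 with an estimated correlation). PCNA, the polymerase clamp, fell by 0.75 and 0.58, RFC3, of the clamp loader, by 0.83 and 0.42, and MCM4, of the replicative helicase, by 0.49 and 0.46, all called in both fits.

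Mitosis genes were lower in 18 and higher in 6 of 32 members (adjusted over the list alone 20 and 6), and the list was called lower (camera adjusted p = 0.0393; adjusted p = 0.465 with an estimated correlation). Its call was lost with the GC offset, where 9 were lower and 4 higher, also over the list alone (adjusted p = 0.734), and without shFITM2 replicate 1 (adjusted p = 0.0765 for the mitosis (G2/M) list). HMMR (−0.66 and −0.20), the kinesin genes KIF11 (−0.67 and −0.24) and KIF23 (−0.55 and −0.26), and the phosphatase gene CDC25C (−0.66 and −0.54, overlapping FAM53C on the opposite strand) fell in both fits. Cytosolic ribosomal protein genes were higher in 21 and lower in 3 of 45 members (adjusted over the list alone 23 and 5), and the list was called higher (camera adjusted p = 0.0258; adjusted p = 0.465 with an estimated correlation). After GC adjustment 12 were higher and 5 lower (adjusted over the list alone 15 and 6; adjusted p = 0.0398; adjusted p = 0.265 with an estimated correlation). The call of the cytosolic ribosomal proteins list, GC-adjusted, was lost without shCTRL replicate 1 (adjusted p = 0.0522), without shFITM2 replicate 2 (adjusted p = 0.056) and with length adjusted for as well (adjusted p = 0.254). RPL37 had 0.97 and 1.22, RPS3 0.58 and 0.75 and RPS9 0.69 and 0.26, called in both fits, and RPS2 had 0.81 and 0.15, called in the group fit alone. The offset used the longest coding transcript, which for RPL37 has 7686 bases (43.2% GC) and may not be the main one expressed. Ribosomal protein genes have many processed pseudogenes, among which reads may be split.

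The p53 target list had 11 members higher and 5 lower of 23, also over the list alone, and was not called (camera adjusted p = 0.224). With the GC offset 8 were higher and 4 lower (adjusted over the list alone 9 and 4), and it was called higher (adjusted p = 0.031; adjusted p = 0.265 with an estimated correlation). That call was lost without shCTRL replicate 3 (adjusted p = 0.216 for the p53 targets list, GC-adjusted). TP53I3 had 1.23 and 0.78, TP53INP1 (overlapped by NDUFAF6 on the opposite strand) 1.03 and 1.43 and the antiproliferative gene BTG2 0.79 and 0.73, whereas CCNG1 had −0.79 and −0.36, each called in both fits. NF-kB and inflammatory cytokine genes were higher in 9 and lower in 1 of 20 members, also over the list alone (camera adjusted p = 0.06). After GC adjustment 4 were higher, in part other members, and none lower, also over the list alone, and the list was called (adjusted p = 0.00853; adjusted p = 0.261 with an estimated correlation). In the group fit the NF-kB and inflammatory cytokines list was called without shCTRL replicate 1, shCTRL replicate 2 or shFITM2 replicate 3 (adjusted p = 0.0269, 0.0177 and 0.0408). PTGS2, the inducible cyclooxygenase, rose by 0.99 and by 1.45 with the GC offset, and RELB by 1.28 and 0.51. NFKB2 had 0.93 and 0.29 (adjusted p = 0.0738 with the GC offset), and TNFAIP2 turned from 0.41 (adjusted p = 0.000704, edgeR) to −0.22 (adjusted p = 0.0623).

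**Figure D3:**
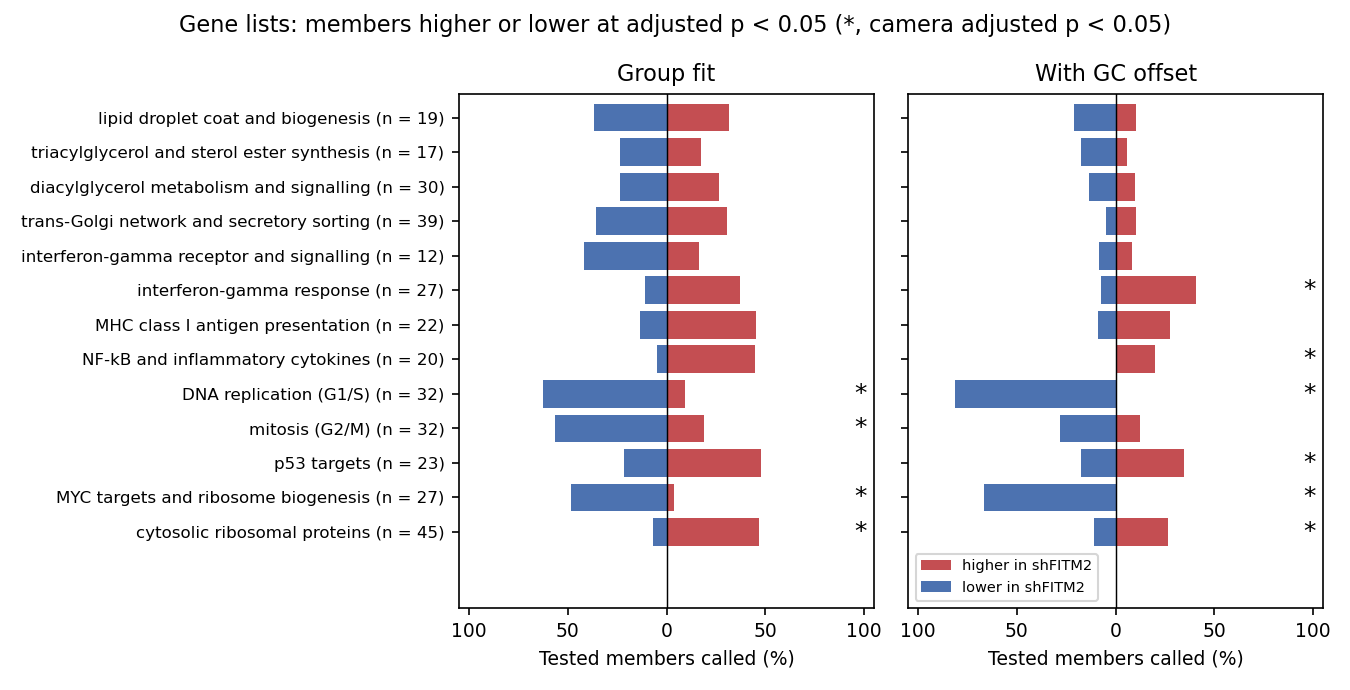
Percent of tested members called higher (right) and lower (left) in shFITM2 for the 13 gene lists described gene by gene, in the group fit and with the GC offset; an asterisk marks a camera adjusted p under 0.05. DNA replication has 20 of 32 members lower in the group fit and 26 of 32 with the GC offset, while mitosis goes from 18 to 9.

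The other lists were not called in either fit, and counts are given as higher and lower members, in the group fit and then with the GC offset. Mitochondrially encoded mRNAs had 1 and 8 of 13 (camera adjusted p = 0.163), then 2 and 5, and the mitochondrially encoded mRNAs list was called without shCTRL replicate 3 in the group fit (adjusted p = 0.000587). All genes of the mitochondrial chromosome together, not these mRNAs alone, took 9.21%, 8.30% and 7.98% of counts in shCTRL and 6.82%, 7.07% and 7.30% in shFITM2. Lysosome and autophagy genes had 15 and 6 of 29 (adjusted p = 0.187), then 6 and 7, MAPK output genes 10 and 4 of 28 (adjusted p = 0.187), then 4 and 3, Wnt and stem cell genes 7 and 2 of 18 (adjusted p = 0.286), then 6 and 2, and enterocyte genes 7 and 2 of 15 (adjusted p = 0.577), then 3 and 2. Goblet cell genes had 2 and 2 of 18 (adjusted p = 0.705), then 2 and 3, and mesenchymal and matrix genes 3 and 2 of 17 (adjusted p = 0.547), then 6 and 3. Epithelial junction and keratin genes had 10 and 6 of 27 (adjusted p = 0.493), then 6 and 6, and the epithelial junctions and keratins list was called without shCTRL replicate 3 in the group fit (adjusted p = 0.0382). Hypoxia and glycolysis genes turned from 12 and 4 of 30 (adjusted p = 0.648) to 5 and 10 (adjusted p = 0.339). Nuclear-encoded oxidative phosphorylation had 14 and 12 of 36 (adjusted p = 0.757), then 10 and 10, and cholesterol synthesis 9 and 7 of 24 (adjusted p = 0.757), then 4 and 5. Fatty acid oxidation had 6 and 6 of 26 (adjusted p = 0.781), then 4 and 7, lipid transport 4 and 1 of 12 (adjusted p = 0.547), then 2 and 2, and lipolysis 5 and 5 of 12 (adjusted p = 0.947), then 1 and 5. The unfolded protein response turned from 12 and 9 of 27 (adjusted p = 0.705) to 4 and 7, NRF2 targets from 13 and 9 of 29 (adjusted p = 0.547) to 6 and 9, and immune checkpoint and NK ligand genes from 6 and 4 of 18 (adjusted p = 0.745) to 1 and 4. Histone genes had 1 and 0 of 13 (adjusted p = 0.757), then 1 and 1.

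The lowest adjusted p among the uncalled lists after GC adjustment belonged to ATF4 targets and fatty acid synthesis. ATF4 targets of the amino acid response went from 8 higher and 9 lower of 23 (camera adjusted p = 0.924) to 1 and 9 (adjusted p = 0.0526). Fatty acid synthesis genes went from 3 and 4 of 15 (adjusted p = 0.913) to 0 and 7 (adjusted p = 0.0526). In the group fit both had medians above 0, 0.21 and 0.11, and means of 0.05 and 0.07, while the test pointed down. Adjusted over the list alone, the group fit gave other counts for lipolysis (6 and 5), ATF4 targets (9 and 9), cholesterol synthesis (11 and 9), oxidative phosphorylation (14 and 13), goblet (2 and 1), epithelial (12 and 7), MAPK (11 and 4), lysosome (15 and 7) and histone genes (0 and 0), and the same counts for the rest of these uncalled lists. After GC adjustment, counts adjusted over the list alone differed for type I interferon-stimulated genes (5 and 2), ATF4 targets (2 and 9), fatty acid synthesis (0 and 8), hypoxia and glycolysis (7 and 11), mitochondrially encoded mRNAs (2 and 6), NRF2 targets (9 and 9), Wnt (7 and 2), enterocyte (4 and 2), epithelial (8 and 8) and MAPK genes (5 and 5). After GC adjustment the median, mean and test also differed in sign for lipolysis (0.03, −0.06, down), immune checkpoint (0.12, 0.02, down), cholesterol synthesis (−0.06, 0.03, down), NRF2 targets (−0.01, 0.07, up) and goblet genes (0.005, 0.05, down).

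Few markers of other cell types passed the expression filter, too few for a list test. Of the fibroblast markers 3 were tested and 1 called, with TAGLN highest at 6.62 CPM, and of the endothelial markers 3 were tested and 1 called, with ESAM highest at 55.8 CPM. None of 3 tested leukocyte markers was called, with LYZ, which intestinal secretory cells also make, at 871 CPM. Of MHC class II genes 4 were tested and 1 called, with CTSS highest at 15.8 CPM.

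**Figure D4:**
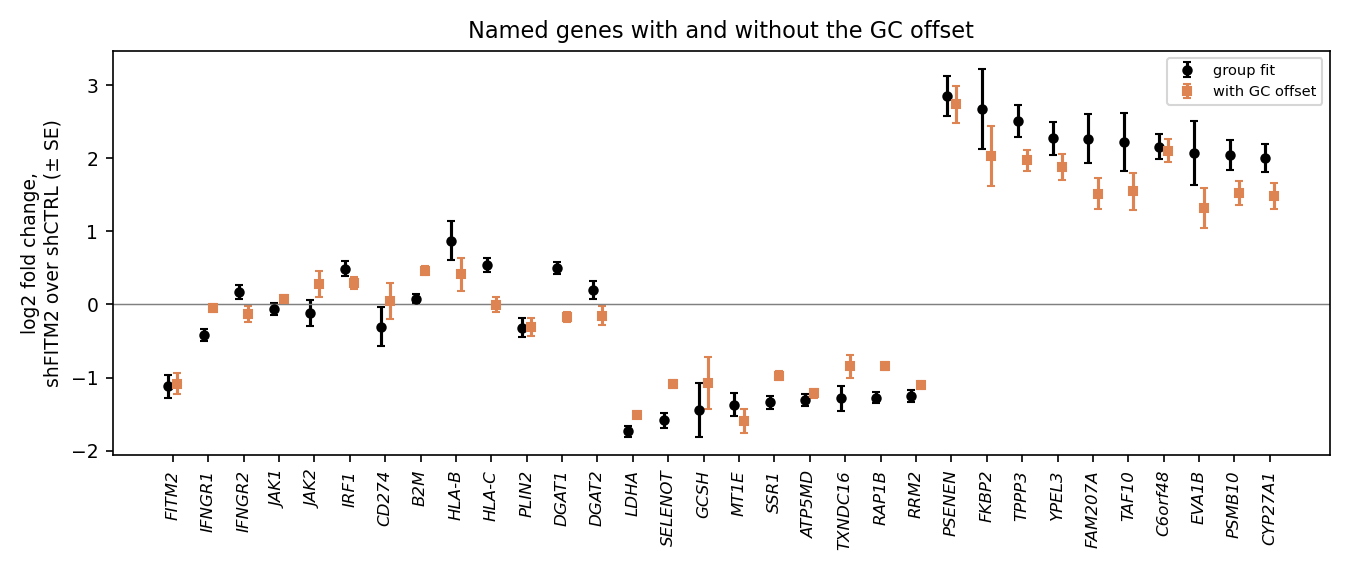
Log2 fold change of shFITM2 against shCTRL (vertical axis, with its SE) for the named genes along the horizontal axis, in the group fit and with the GC offset. FITM2 moves from −1.12 to −1.08 and LDHA from −1.74 to −1.51, while IFNGR1 moves from −0.42 to −0.05 and HLA-C from 0.54 to −0.002.

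The GC slopes of the libraries separated the groups (mean −0.22 ± 0.139 in shCTRL and 0.22 ± 0.042 in shFITM2, SD, n = 3), so a change that follows GC content was not assigned to the knockdown or to the libraries. The labels name a single kind of FITM2 hairpin, and effects of its sequence were not separated from those of FITM2 loss.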

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

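Tests of the GC offset, alone or with length, were chosen after the result was seen; all other settings were planned. FITM2 kept its direction and call under every setting run for single genes, with a FITM2 log2 fold change from −1.002 to −1.225 over the left-out libraries. The lipid droplet coat and biogenesis list stayed uncalled under every setting run for lists (adjusted p from 0.0695 to 0.996). The count of genes changed in shFITM2 against shCTRL, 7205, was 7206 with DESeq2 size factors, 7221 with library totals, 7292 with no filter, 7166 with a mean of at least 1 CPM, 6587 with the DESeq2 Wald test, 7417 with limma-voom and 7178 without mitochondrial genes. It fell to 4227 (1837 genes higher in shFITM2 and 2390 genes lower in shFITM2) with the GC offset and to 4202 (1832 and 2370) with length as well, which remove a trend that differs between the groups. It was 345 (269 and 76) against a 1.5-fold change, a stricter hypothesis by construction, and 2362 genes were higher at an adjusted p under 0.01. The 780 genes changed at least 2-fold became 258 and 253 with the GC offset and with length as well. Leaving out 1 library gave 5338 to 9008 genes (2590 to 4505 higher, 2748 to 4503 lower), and 569 to 1417 genes changed at least 2-fold, the highest without shCTRL replicate 3. For the genes changed in shFITM2 against shCTRL, GC-adjusted, it gave 2760 to 5589 (1177 to 2522 genes higher in shFITM2, GC-adjusted, and 1583 to 3067 genes lower in shFITM2, GC-adjusted), the lowest without shFITM2 replicate 1 and the highest without shCTRL replicate 3. Gene lists called in shFITM2 against shCTRL, 4 in the group fit, were 0 with an estimated correlation in camera (1 at an unadjusted p under 0.05), 20 with fry, 8 with no filter (MHC class I, NF-kB, mitochondrially encoded and lysosome lists added) and 3 to 6 with 1 library left out. The 6 gene lists called, GC-adjusted, were 0 with an estimated correlation (6 at an unadjusted p under 0.05), 17 with fry and 5 to 9 with 1 library left out. For the interferon-gamma response list, the camera adjusted p = 0.273 became 0.0069 with the GC offset, 0.00527 with length as well, and 0.193 to 0.655 with 1 library left out. Its adjusted p with fry, which tests a list against no change rather than against other genes, was 0.00148. Among called genes, the sign turned with the GC offset and with length as well for HLA-C log2 fold change −0.002 and −0.013, DGAT1 log2 fold change −0.176 and −0.157, and TNFAIP2 log2 fold change −0.219 and −0.201. Of 78 named genes besides FITM2, 62 stayed on the same side of the threshold with the GC offset, of which the uncalled IFNGR2, JAK1, JAK2, CD274 and DGAT2 turned sign in both offset fits, and at least 75 stayed under each setting without an offset that was run for single genes (the stricter thresholds were run for counts alone). Except where a construction is named, the cause was not tested. FITM2 had 84 to 250 reads per library, which limits its precision.

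Samples with the same replicate number did not deviate together (correlations of −0.06, −0.019 and −0.149), so the numbers were not taken as pairs. With the replicate block, the count of genes changed in shFITM2 against shCTRL was 6729 (3444 genes higher in shFITM2 and 3285 genes lower in shFITM2), that of genes changed in shFITM2 against shCTRL, GC-adjusted, was 4114, and 3 lists were called. The FKBP2 log2 fold change lost its call with the block (2.84, adjusted p = 0.0576), as did the mitosis (G2/M) list (adjusted p = 0.0505). The block changed no other call among the named genes and lists of the group fit.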

Other observations

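The tests of the splits of the libraries, of base composition around the hexamer, and of the CCAACT mRNAs in shCTRL replicate 3 were chosen after the results were seen, as were the genes named in the next sentences. Several mRNAs of growth arrest and of FOXO transcription factor programmes were higher in shFITM2 in both fits. FOXO4 itself had a log2 fold change of 1.56 and 1.23 with the GC offset (adjusted p = 1.33e-05 and 2.96e-07, edgeR), the pro-apoptotic BH3-only genes BBC3 2.00 and 1.11 and BMF 1.40 and 1.12, the autophagy gene GABARAPL1 1.17 and 1.196, TXNIP 0.51 and 0.74, CCNG2 0.33 and 0.68, and the CDK inhibitor gene CDKN1B 0.30 and 0.37. FOXO1 went the other way, with −0.44 and −0.32. Of 20 such genes, 11 were higher and 2 lower in the group fit and 12 and 1 with the GC offset; they were picked partly because they rose, so the count is no test of the group.

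The metallothionein genes MT2A and MT1E had −1.07 and −1.37, and −1.76 and −1.59 with the GC offset (adjusted p = 0.0055 and 5.59e-05, edgeR), while MT1X, near 1.04 CPM in shCTRL, was not called. RHOA, the GTPase of actin contractility, had −1.05 and −0.98, from 511 ± 27.1 to 247 ± 3.68 CPM (SD, n = 3). The snoRNA host gene SNHG4 had −1.002 and −0.74. The homeobox transcription factor gene PROX1 rose by 1.27 and by 1.63 with the GC offset, and the calcium-binding gene S100A2 by 1.78 and 1.55. A family of 50 short mRNAs had 18 members higher and 1 lower in the group fit, 12 and 5 with the GC offset, and 9 and 8 with length adjusted for as well.

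Fold changes rose with transcript GC content. In long non-coding RNAs, which have no codons, the slope was 0.386 ± 0.0189 per 10 points of GC (SE, 637 genes), against 0.444 ± 0.0034 in 10899 protein-coding genes, a ratio of 0.869 (95% bootstrap interval 0.781 to 0.955). This class includes antisense genes. The strand setting of the counting is not known, so their counts may include reads of overlapping coding mRNAs. Apart from that limit, the ratio argues against codon usage or translation as the source. A GC bias of library preparation or amplification would give such slopes, and the slopes of shCTRL libraries also differed among themselves (−0.33 to −0.07). A change of the cells themselves that follows GC content remains open and untested, since the trend separates the groups. The 6 libraries allow 10 splits, too few to judge chance: 1 of the 10 gave as many genes as the real 7205, the highest other giving 0 in edgeR (at most 476 at an unadjusted p under 0.05), likewise 1 of the 10 for the 4227 with the GC offset, the highest other giving 0 (at most 513), and for lists 1 of the 10 gave as many as the real 4, the highest other giving 3.

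The library of shCTRL replicate 3 lay part of the way to shFITM2. Over called genes its fraction of the way was 0.453 in the group fit and 0.427 with the GC offset (95% interval 0.407 to 0.446), a drop of 0.0263. The other shCTRL libraries had 0.0861 and 0.0118 with the GC offset. The intervals of gene sets given here come from resampling genes, and that of FITM2 from its counting error. None of them measures the spread between libraries. The 0.427 left with the offset argues against its GC trend as the whole cause, since the simulated trend alone left 0.0866. The group-fit fraction could come from that trend alone, which gave 0.461 there. Near-equal fractions before and after the offset do not decide whether shFITM2 RNA or reads were mixed in. Mixing was simulated on top of the library's own GC slope. A share of 0.4 gave 0.651 in the group fit and 0.432 with the GC offset, and a share of 0 gave 0.461 and 0.0866. The shift of mRNAs with CCAACT in the 3' UTR lay at 0.0997 of the way (−0.09 to 0.244) and FITM2 at 0.152 (−0.0786 to 0.357). DNA replication genes lay at 0.144 (0.0308 to 0.266) and MYC targets at −0.0236 (−0.272 to 0.158). Interferon-gamma response (−1.19 to 0.388), NF-kB (−1.43 to 0.412), ribosomal protein (−1.74 to 0.609) and p53 target genes (−4.18 to 4.22) had wide intervals, and the last pair include 0.427. These values do not decide on mixing. On the log2 scale used, a mixed library lies further along for genes that rose than for genes that fell. FITM2, the CCAACT mRNAs, replication genes and MYC targets all fell. Of the 258 genes called at least 2-fold with the GC offset, 185 were higher. What set this library apart was not found, and a difference between cultures could not be tested.

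Messenger RNAs with the hexamer CCAACT in the 3' UTR were lower in shFITM2, the lowest of 4094 hexamers after GC and length adjustment (z = −6.12; permutation p = 0.001, the smallest that 1000 permutations give). Their mean shift against genes without it was −0.048 ± 0.006 on the log2 scale (SE, 2747 of 9269 genes, not independent replicates). The mean residual was 0.014, −0.024 and −0.057 for 0, 1 and 2 or more sites. The medians of the adjusted log2 fold change were closer together, at −0.018, −0.032 and −0.034, and 21.8%, 23.4% and 25.8% of these genes were called lower. Of the 10 genes with the largest fall, 9 were searched and 6 carry the hexamer: LDHA, RRM2, SELENOT, SSR1, ATP5MD and RAP1B. GCSH and MT1E are among those without it. Of all genes searched, 29.6% carry it, and the mean shift of −0.048 is small beside the falls of these 6 genes. Other hexamers of the same bases reached a z of −2.51 at the lowest, and the reverse complement a shift of −0.004 ± 0.008, which argues against base composition. A candidate explanation is pairing of the FITM2 hairpin's seed with these sites: the FITM2 transcript holds CCAACT, at position 257, but 57.4% of all hexamers are in it too, genes with the hexamer in the coding sequence alone shifted by −0.022 ± 0.007, close to the bound set for that idea, and the hairpin sequence is not given in the sources used here. Extended by 1 base, the words in FITM2 had mean residuals of −0.063 ± 0.009 (ACCAACT) and −0.072 ± 0.011 (CCAACTA). Of the words absent from it, GCCAACT, CCCAACT and TCCAACT had −0.062 ± 0.01, −0.027 ± 0.008 and −0.012 ± 0.01. CCAACTC, CCAACTG and CCAACTT, also absent, had −0.026 ± 0.009, −0.037 ± 0.009 and −0.029 ± 0.009. For the last base, the word found in FITM2 was the lowest. For the first base, GCCAACT, absent from FITM2, was about as low as ACCAACT, so these words do not decide on pairing. No prediction was set for them beforehand. Replication genes without the site still had a median of −0.28 (24 genes) and MYC targets without it −0.36 (23 genes). Pairing at 3' UTR sites would not reach those mRNAs directly, and indirect effects of the hairpin on them were not tested.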
